A study of Mus musculus with 2 samples.

How the data were processed

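H3K9ac ChIP-seq was performed on limb tissue of mouse embryos at embryonic day 13.5, with 2 biological replicates of a single group and embryos of both sexes in each. Peak lists in narrowPeak layout were deposited for each replicate, for both replicates together (pooled) and as a replicated list. Per the notes deposited with the lists, each replicate's list was called on that replicate's alignments against a control, the pooled list on both replicates' alignments with both controls, and the replicated list was drawn from the pooled list and both replicate lists. Per the labels the assembly is mm10. The aligner, the peak caller, their versions and the rule that makes a peak replicated are not given in the sources used here. All replicated peaks are pooled peaks, so folds and p-values in the replicated list are those of the pooled data.

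The values in the deposited lists are the authors' ratio (fold over control) per peak and the −log10 of the authors' p and q per peak, all without replicate error. The fold values fit (pileup + 1)/(background + 1), and at the 5 commonest value pairs of each list the −log10 p values fit a Poisson upper tail at that background to within 8.61e-05. Peaks were taken to lie on the genome-wide background if they met these fits to within 0.0005 in fold and 0.01 in −log10 p, and so selected they are 63.2% of peaks in replicate 1, 64.0% in replicate 2 and 64.5% in the pooled list. The background pileup recovered in this way is 3.11, 2.23 and 5.40, a ratio of 1.39 between replicates 1 and 2, or 1.36 per bp after dividing by the smallest peak width (180 and 175 bp). It is a relative measure of depth and not a read count, and total depth is unknown. The largest p kept by the authors was 0.00981 in replicate 1, 0.00955 in replicate 2 and 0.00974 in the pooled list, a permissive limit: 68.5%, 57.0% and 69.5% of peaks had a −log10 q of at least 2, and 98.2% of replicated peaks did. A shallower library has coarser fold steps (0.310 per read in replicate 2, 0.243 in replicate 1), which limits the precision of weak peaks.

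Peaks on the autosomes, X and Y were analysed, and peaks on scaffolds were left out (9, 7, 9 and 7 in the replicate 1, replicate 2, pooled and replicated lists). Genes and transcription starts came from GENCODE release M21 on GRCm38, the build of the lists, since no peak passes a chromosome end, and promoter sequence came from the GRCm38 genome. There were 132721 starts and 21911 protein-coding genes, after leaving out 27 repeated symbols. A peak was at a promoter if it overlapped the window 1 kb either side of any annotated start, and otherwise in an exon, an intron or intergenic. Peaks of different lists were matched when the overlap reached 50% of either peak, beside 100 random placements of the list on the same chromosomes outside assembly gaps of at least 1000 bp. Promoter CpG is the observed/expected ratio in the 1 kb window around the gene's outermost start.

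The comparisons were the overlap of the replicates, recovery by decile of rank, the place of peaks, 20 gene lists, 12 intervals, X against autosomes and CpG classes. Gene lists were tested with Fisher's exact test (two-sided) against all other protein-coding genes, with Benjamini-Hochberg adjustment over 20 lists and a threshold of 0.05, and against 10000 random lists matched on promoter CpG in 5 classes (permutation p). Intervals were set against 10000 random intervals of the same length. The lists, intervals, main tests and the naming rule were fixed before the data were examined. The rule named the 10 genes with the highest promoter fold, the 10 genes in the widest runs of peaks joined within 1000 bp, the 4 highest members of each list and up to 4 unmarked members where most were marked, the 5 strongest peaks over 5 kb from a start, the 3 strongest unpartnered peaks per replicate, and Tbx5, Tbx4, Pitx1, Shh, Fgf8, Sox9, Hoxd13 and Hoxa13. Other list members named as unmarked, the lower-ranked members, the Y-linked genes and the HoxA to HoxD breakdown were chosen after their values were seen. Ahsp, in the erythroid list, is not in the annotation and was left out.

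On simulated data the overlap step found 100% of planted partners and 0% of those overlapping by less than the limit, over 4000 peaks. With 21911 genes, Fisher's exact test without adjustment over lists called 98.5% of simulated lists of 18 genes marked at a 95% rate. Shorter lists were not simulated. The same test called 4% of lists at the background rate. It called 87.5% of CpG-rich lists with no other effect, against 2.5% for the matched lists, so both tests are given. The power of the adjusted test used on the real lists was not simulated, and the 98.5% does not carry over to it. The real epidermis and epithelium list had 16 of 18 genes marked and missed the adjusted threshold (Fisher's exact test, p = 0.0463, adjusted p = 0.0661). Alternatives were the overlap rule (1 bp, or 50% of both peaks), a −log10 q of at least 2, lists of equal length, promoter windows of 500 bp and 2.5 kb, outermost starts only, the pooled list, each replicate's own list, covered bases, a CpG limit of 0.75, ranking on −log10 p, and, chosen after seeing the data, replicated peaks found in both replicates and genes without a neighbouring coding start within 2 kb. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.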

Results

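Acetylation of lysine 9 on histone H3 (H3K9ac), a chromatin mark found at active promoters and enhancers, was measured by chromatin immunoprecipitation and sequencing in limb tissue of mouse embryos of the B6NCrl strain at embryonic day 13.5, pooled from both sexes. The labels say limb and do not separate forelimb from hindlimb. There were 2 biological replicates of a single group, so the design implies no contrast between conditions. The comparisons below concern the agreement of the replicates and the place of the peaks among limb genes. On the chromosomes, replicate 1 had 73200 peaks covering 39.0 Mb, replicate 2 had 95631 peaks covering 43.8 Mb, the list called on both replicates together (pooled) had 120388 peaks, and the authors' replicated list had 42981 peaks covering 40.9 Mb (1.54% of the genome). Read totals are not in the peak lists, and depth is known only through the genome-wide background pileup implied by the fold and p columns, which was 3.11 in replicate 1 and 2.23 in replicate 2. Fold over control is the authors' value for each peak and is compared only within a list. A gene's promoter fold is that of the strongest replicated peak within 1 kb of any of its annotated starts, and 0 stands for a gene with no such peak. Intervals on shares are Wilson 95% intervals over peaks or genes and cover counting error only, not variation between litters.

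The strongest H3K9ac in both replicates lay at promoters such as those of Hoxa10, Arid1a and Gas1, and sites of this strength were shared. Hoxa10, a homeobox gene of the posterior HoxA cluster, had a promoter fold of 41.6 in replicate 1 and 49.2 in replicate 2. These values stood at percentiles 99.989 and 99.997 of the peaks in those lists. Arid1a, a subunit of the BAF chromatin remodelling complex, had 47.5 and 43.4, and Gas1, a cell surface receptor for hedgehog ligands, had 41.6 and 50.5. Among the strongest decile of peaks ranked by fold, 7320 of 7320 in replicate 1 (100%, 99.9 to 100) had a partner in replicate 2, and 9562 of 9563 in replicate 2 (99.99%, 99.9 to 100) had a partner in replicate 1. A partner was a peak overlapping at least 50% of either peak's length. Agreement fell with rank, to 47.1% in decile 4 and 20.9% in decile 10 of replicate 1, and to 30.8% and 11.4% in replicate 2. Over whole lists 34726 of 73200 replicate 1 peaks (47.4%, 47.1 to 47.8) and 35138 of 95631 replicate 2 peaks (36.7%, 36.4 to 37.0) had a partner. The mean over 100 random placements of the other list was 3.0% and 2.30%.

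**Figure D1:**
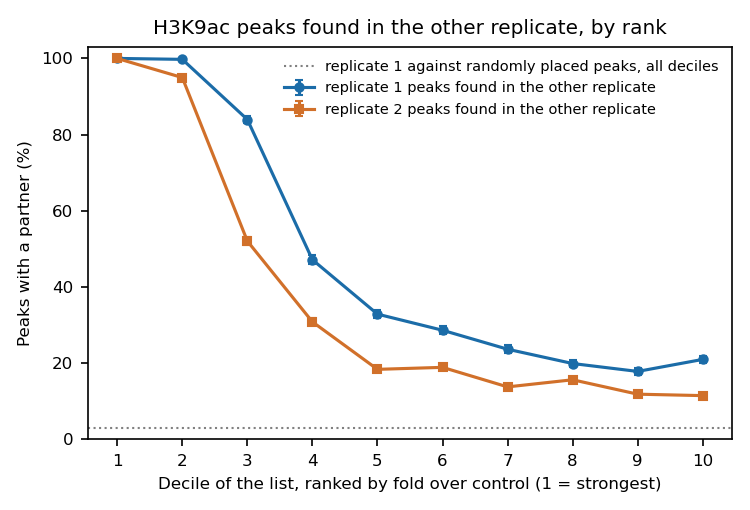
Share of each replicate's H3K9ac peaks with a partner in the other replicate (percent, y axis) by decile of the list ranked on fold over control (x axis, 1 the strongest); bars are Wilson 95% intervals and the dotted line is replicate 1 against randomly placed peaks (3.0%). The share is 100% in replicate 1's strongest decile and 20.9% in its weakest.

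Peaks found in a single replicate were narrow and weak, and the strongest of them lay at genes whose promoter was marked in the replicated list. In replicate 1, the 38474 peaks without a partner had a median width of 220 bp and a median fold of 2.92, against 588 bp and 5.07 for the 34726 shared peaks. Of the former, 19.2% (18.8 to 19.6) overlapped a promoter window, against 63.9% (63.4 to 64.4) of the latter. Replicate 2 had 60493 peaks without a partner, with a median width of 212 bp, a median fold of 3.10 and 17.5% (17.2 to 17.8) at promoters, against 573 bp, 5.27 and 63.8% for its shared peaks. The strongest peaks without a partner lay at Tmem25 (fold 8.03), Eif3l (7.79) and Dedd2 (7.55) in replicate 1, and at Arhgap28 (15.3), Pcnt (8.36) and Chn1 (7.74) in replicate 2. All 6 genes had a promoter peak in the replicated list, as did 66.4% of all protein-coding genes. Their folds there were 9.9996 at Tmem25, 16.7 at Eif3l, 16.6 at Dedd2, 14.2 at Arhgap28, 12.2 at Pcnt and 16.7 at Chn1.

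Of the replicated peaks, 88.8% (88.5 to 89.1) were found in replicate 1, 89.0% (88.7 to 89.3) in replicate 2 and 33978 of 42981 (79.1%, 78.7 to 79.4) in both. The 9003 others were weaker, with a median fold of 3.06 against 5.16, and 22.3% (21.4 to 23.2) of them lay at promoters against 60.7% (60.1 to 61.2). The share found in both was 54.1% when an overlap of 50% was asked of both peaks, and 61.2% when all 3 lists were cut to peaks with a −log10 q of at least 2.

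The replicated peaks were concentrated at promoters. The 10 protein-coding genes with the highest promoter fold were Arid1a and Nfib (both 52.0), Sfpq (51.4), Gas1 (51.1), Tnrc18 (50.6), Hoxa10 and Hoxa9 (50.5, a single shared peak), Actg1 (50.2), Rps19 (49.7) and Eef1a1 (49.4). They include a nuclear factor I transcription factor (Nfib), an RNA-binding protein of paraspeckles (Sfpq), cytoplasmic gamma-actin (Actg1), a ribosomal protein (Rps19) and a translation elongation factor (Eef1a1). The Arid1a peak spans chromosome 4 positions 133750020 to 133758022 in GRCm38 (mm10), covering an annotated start at 133753611. The Nfib peak (chromosome 4, 82502594 to 82508937) and the Eef1a1 peak (chromosome 9, 78480062 to 78481707) lie at alternative starts, at 82505308 and 78480841, and not at the outermost annotated start. Of 42981 replicated peaks 52.6% (52.1 to 53.1) overlapped a window of 1 kb either side of an annotated start, against 9.09% of randomly placed peaks. Exons held 5.61% (random 3.13%), introns 26.6% (random 39.1%) and intergenic sequence 15.2% (random 48.7%). Promoter peaks had a median fold of 8.80 and a median width of 1074 bp, and intronic peaks 3.28 and 441 bp. Of 21911 protein-coding genes, 14544 (66.4%, 65.7 to 67.0) had a promoter peak. The promoter share was 29.6% in the longer pooled list.

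The widest runs of replicated peaks, joined within 1 kb, lay over the HoxA and HoxD clusters, followed by transcription factor genes and a few others. The run containing Hoxa10 spanned 53622 bp at the HoxA cluster (chromosome 6, 52215560 to 52269181). The run containing Hoxd11 spanned 47258 bp at the HoxD cluster (chromosome 2, 74653812 to 74701069). Both extend past the posterior end of the cluster, at the Hoxa13 start (52260880) and the Hoxd13 start (74668310). Runs of 26446 bp at Ebf3, 25673 bp at Zfhx3, 23994 bp at Lmx1b, 21138 bp at Nr2f2, 21037 bp at Midn, 20248 bp at Bahcc1, 17265 bp at Rarg and 17254 bp at Tbx15 followed. Lmx1b specifies dorsal identity in the limb, and Rarg encodes a retinoic acid receptor. The Zfhx3, Nr2f2 and Tbx15 peaks lie at starts inside the outermost annotated start of the gene.

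Among transcription factors that pattern the limb, all 31 listed genes had a promoter peak in the replicated list and in each replicate's own list. Prrx1, a homeobox gene of limb mesenchyme, had a promoter fold of 45.6 (chromosome 1, 163306066 to 163315515). Hoxa11 had 38.7, Gli3, the transcriptional effector of hedgehog signalling, had 38.3, and the mesenchymal factor Twist1 had 38.3. Tbx5, required for forelimb initiation, had 22, and Pitx1 and Tbx4, which act in the hindlimb, had 23.3 and 20.0. Their order differed in the lists of replicates 1 and 2, where Tbx5 had 26.0 and 25.3, Pitx1 19.7 and 21.4, and Tbx4 16.8 and 20.8. Hoxa13 and Hoxd13, which pattern the digits, had 38.3 and 27.2 in the replicated list. The lowest were Dlx6 (9.53) and Meis2 (7.25). The list's share of 100% (89.0 to 100) was 33.7 percentage points above that of other protein-coding genes (Fisher's exact test, two-sided, adjusted p = 2.50e-05 over 20 lists, 3.69e-06 to 0.000157 over 9 alternatives of that test). Its median fold of 21.9 exceeded 99.99% of the medians of random lists matched on promoter CpG, and the median of those medians was 13.8. Presence of a peak did not separate the list from matched lists, which averaged 91.1% (permutation adjusted p = 0.169). With every member already marked, that test could not have called an excess, so it decides nothing about one. In this and the tests below the units are genes, so each p describes these peak lists and not variation between embryos. Genes that share a peak, such as Hoxa9 and Hoxa10, are counted separately, as if independent.

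Promoter peaks were counted in each Hox cluster, with no test between clusters. All 11 HoxA, 9 HoxC and 9 HoxD genes had a promoter peak, while 5 of 10 HoxB genes did (Hoxb2, Hoxb4, Hoxb5, Hoxb6 and Hoxb9), and 5 and 8 of 10 in the lists of replicates 1 and 2. Median promoter folds were 44.6 for the 4 HoxA genes of groups 9 to 13 and 27.2 for the 5 such HoxD genes, against 6.46 for the 5 such HoxC genes. The 2 such HoxB genes had a median of 1.15, from 2.30 at Hoxb9 and 0 at Hoxb13. Both had a peak in replicate 2's list (4.03 and 3.09) and neither in replicate 1's. Within HoxA the genes of groups 1 to 8 had a median of 9.87, and within HoxD of 8.44. Folds and counts of neighbouring genes are not independent, since a peak can cover several starts (Hoxa9 with Hoxa10, Hoxd11 with Hoxd12). The interval and tests on the whole family do not allow for this. No HoxB gene exceeded 8.75, the value at Hoxb2. Hoxb1, Hoxb13, Hoxb3 and Hoxb7 had no replicated promoter peak but had peaks of fold 2.75 to 3.10 in a single replicate's list, and Hoxb8 had none in either. Over the whole family 34 of 39 genes (87.2%, 73.3 to 94.4) had a peak (Fisher's exact test, adjusted p = 0.0129, 0.000157 to 0.0367 over the alternatives of that test), against 86.9% in CpG-matched lists (permutation adjusted p = 1). The family's median fold of 7.98 stood at percentile 0.225 of the medians of matched lists, and the median of those medians was 12.9.

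**Figure D2:**
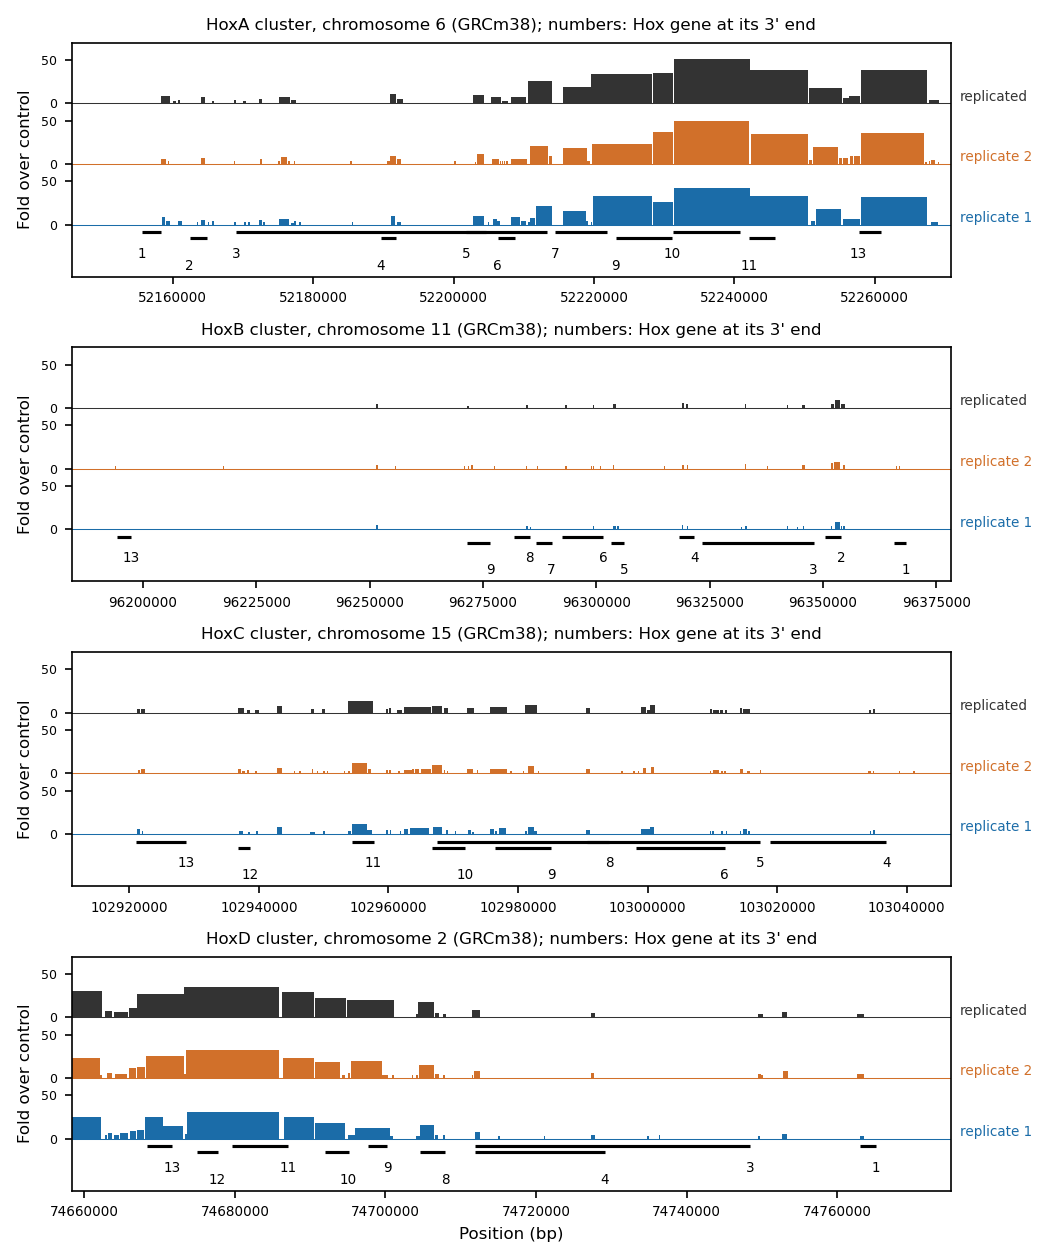
H3K9ac peaks over the 4 Hox clusters in GRCm38: each block is a peak drawn to its width (x axis, bp) and with its fold over control as height (y axis) in replicate 1, replicate 2 and the replicated list, above gene spans numbered at their 3' ends. Blocks over the posterior HoxA genes reach 50.5 in the replicated list and those over Hoxd11 reach 34.4, while no HoxB gene exceeds 8.75.

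Most limb signalling genes were marked, at lower fold than CpG-matched genes. Wnt5a, which directs outgrowth along the limb, had a promoter fold of 31.9, Bmp2 had 24.5, Bmp7 14.7 and the BMP antagonist Nog 14.3. Fgf10, the mesenchymal signal of limb outgrowth, had 10.3. Fgf8, an ectodermal ridge ligand, had 7.34. Shh, the ligand of the zone of polarizing activity, had no replicated promoter peak and a peak of fold 3.10 in replicate 2 alone, and Fgf4 had a peak of 3.18 in replicate 1 alone. In all, 19 of 21 genes had a peak (90.5%, 71.1 to 97.3), above other genes by Fisher's exact test (adjusted p = 0.0386, 0.00445 to 0.0564 over its alternatives). The list's median fold of 6.81 stood at percentile 0.38 of the medians of matched random lists (median of those medians 13). Against CpG-matched lists the share did not pass the test (permutation adjusted p = 0.867).

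In the chondrocyte list 19 of 20 genes had a promoter peak (95%, 76.4 to 99.1), above other genes by Fisher's exact test (adjusted p = 0.0115, 0.00203 to 0.0257 over its alternatives) and above CpG-matched lists at 73.9% (permutation adjusted p = 0.0207). Sox6 (24.4) and Sox9 (23.7), transcription factors of chondrocyte differentiation, led the list, followed by the cartilage collagen Col2a1 (22; chromosome 15, 97999337 to 98005850) and Trps1 (20.6). Snorc had no replicated peak, and one of 3.41 in replicate 1's list. In the osteoblast and hypertrophic cartilage list, the regulators Runx2 (17.0), Satb2 (16.3), Mef2c (8.59) and Sp7 (7.19) were marked, as were the alkaline phosphatase gene Alpl (4.13) and the osteoblast membrane protein gene Ifitm5 (4.13). The 10 other members, Bglap, Bglap2, Col10a1, Dmp1, Ibsp, Mepe, Mmp13, Phex, Sost and Spp1, had no replicated promoter peak (Col10a1 had one of 3.16 in replicate 1's list). Its 6 of 16 (37.5%, 18.5 to 61.4) were below other genes by Fisher's exact test (adjusted p = 0.0498, 0.00875 to 0.105 over its alternatives), a call absent against matched lists at 38.5% (permutation adjusted p = 1) and from replicate 1's own list (Fisher's exact test, adjusted p = 0.0901). Tendon and joint genes had a peak in 12 of 15 cases (80.0%, 54.8 to 93.0), which did not pass the test (Fisher's exact test, adjusted p = 0.458; permutation adjusted p = 0.650 against CpG-matched lists). Six1 (25.1), Scx (20.0, a peak shared with the start of Bop1), Six2 (17.2) and Mkx (11.9) were highest, and Kera, Prg4 and Tnmd had none.

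For genes of muscle, epithelium, vessels and nerve sheath, the median promoter fold over all members was 3.28, 4.37, 4.11 and 5.11. The median of the medians of CpG-matched random lists was 1.64, 4.93, 6.51 and 5.0 (lists at percentiles 65.9, 41.2, 20.0 and 50.7). Skeletal muscle genes had a peak in 11 of 20 cases (55.0%, 34.2 to 74.2; Fisher's exact test, adjusted p = 0.404; permutation adjusted p = 1 against CpG-matched lists), with Des at 5.62, Pax7 at 4.22, Myod1 at 4.15 and Cdh15 at 3.91. Among its contractile genes Tnnt1 had a peak (3.73), and Acta1, Actc1, Myh3, Myh8, Myl1, Tnnt3 and Ttn had none in the replicated list. Actc1 (3.16) and Tnnt3 (3.36) had one in replicate 1's list and Myh3 (3.10) in replicate 2's. Of the epidermis and epithelium genes 16 of 18 (88.9%, 67.2 to 96.9) had a peak, led by Krt10 (15.8), Lor (12.7), Krt1 (11.9) and Epcam (7.97). The Krt10 and Krt1 peaks lie at starts inside the outermost annotated start, at 99386097 and 101846594. The Lor peak ends at 92082191, within its promoter window but short of the start at 92083142. Krt14 and Krt15 had no replicated peak, though Krt15 had peaks of 2.68 and 3.41 in the lists of replicates 1 and 2. The list missed the threshold against other genes (Fisher's exact test, adjusted p = 0.0661, 0.00764 to 0.811 over the alternatives of that test) and passed it against CpG-matched lists at 59.7% (permutation adjusted p = 0.0207). Its excess over other genes was 22.5 percentage points, but 6.55 with a 500 bp window and 4.12 with outermost starts only. Matched lists were not tested under those settings. Endothelial genes had a peak in 11 of 16 cases (68.8%, 44.4 to 85.8; adjusted p = 1 both by Fisher's exact test and by permutation against CpG-matched lists), with Ets1 (16.9), Egfl7 (12.5), Kdr (10.3) and Sox18 (6.87) highest. The vascular receptors Tek and Tie1 had no peak. Among Schwann cell and neural crest genes 8 of 11 (72.7%, 43.4 to 90.3; Fisher's exact test, adjusted p = 0.801; CpG-matched permutation adjusted p = 0.650) had a peak, with Mpz (23.3, a peak shared with the start of Sdhc), Ngfr (7.97), Erbb3 (7.50) and Mbp (6.57) highest and Cdh19, Foxd3 (3.16 in replicate 1's list) and Plp1 without.

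Blood cell genes were marked in a minority of cases. In the erythroid list Klf1 (13.3), Nfe2 (9.9996), Epor (6.72), Gypa (5.09) and Tal1 (4.84) had peaks. The globin genes Hba-a1, Hba-x, Hbb-bh1, Hbb-bs and Hbb-y, the regulator Gata1, and Alas2 and Slc4a1 had none in the replicated list or in either replicate's own list. Hba-a1 has a near-identical copy, so its reads are uncertain. The erythroid count of 5 of 13 (38.5%, 17.7 to 64.5) did not pass the test (Fisher's exact test, adjusted p = 0.0635; CpG-matched permutation adjusted p = 1). The macrophage list had 3 of 14 genes with a peak (21.4%, 7.57 to 47.6), Aif1 at 3.75, C1qc at 2.97 and Spi1 at 2.97, below other genes by Fisher's exact test (adjusted p = 0.00313, 0.000566 to 0.0734 over its alternatives). Replicates 1 and 2 listed 4 and 6 of the 14. The call was not present in replicate 2's own list (Fisher's exact test, adjusted p = 0.0734), nor against CpG-matched lists at 27.1% (permutation adjusted p = 1).

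In the lists of tissues outside the limb the share of genes with a replicated promoter peak ran from 0% for hepatocyte genes to 44.4% for neuronal genes. None of the 18 hepatocyte genes, Alb, Afp and Hnf4a among them, had a replicated promoter peak (0%, upper Wilson bound 17.6%; Fisher's exact test, adjusted p = 2.97e-08; CpG-matched lists 32.6%, permutation adjusted p = 0.0080). Single replicates listed 2 of the 18 each. Of 1134 olfactory receptor genes, 4 had a peak (0.353%, 0.137 to 0.903), Olfr94 (7.31), Olfr1033 (4.06), Olfr71 (3.12) and Olfr1342 (3.12), against 69.98% of other genes and 19.2% in CpG-matched lists (permutation adjusted p = 0.0040, from the smallest p that 10000 lists can give). Replicates 1 and 2 listed 9 and 13 of them. The germ line list had 5 of 16 (31.3%, 14.2 to 55.6; Fisher's exact test, adjusted p = 0.0129, 0.00239 to 0.138 over its alternatives), with Gdf9 (25.5) far above Dazl (5.87), Prm1 (3.59) and Tnp2 (2.67). Replicates 1 and 2 listed 4 and 6 of the 16. The call was lost in the pooled list (Fisher's exact test, adjusted p = 0.138) and against CpG-matched lists at 55.7% (permutation adjusted p = 0.0554). The Gdf9 peak (chromosome 11, 53429626 to 53430837) also covers the promoter window of Uqcrq, a mitochondrial respiratory chain gene. The lung, pancreas and gut epithelium list had 5 of 14 (35.7%, 16.3 to 61.2; Fisher's exact test, adjusted p = 0.0394), with Sftpc (31.4), Foxa1 (6.41), Cdx1 (3.59) and Nkx2-1 (3.28) highest. The Sftpc peak (chromosome 14, 70517965 to 70521198) overlaps the promoter window of Bmp1. Replicate 1 had a peak of fold 29.6 in the Sftpc window and replicate 2 had none there. That replicate 1 peak nevertheless had a partner in replicate 2, as all replicate 1 peaks with a fold above 12.5 did. The replicate 2 peak did not reach the Sftpc window. The list was below CpG-matched lists at 65.6% (permutation adjusted p = 0.0180), and its median fold stood at percentile 0.83 of theirs. Against other genes it did not pass in replicate 1's own list, with 6 of 14, or in replicate 2's, with 7 of 14 (Fisher's exact test, adjusted p = 0.116 and 0.213, 0.00875 to 0.677 over the alternatives of that test). Neuronal genes had a peak in 8 of 18 cases (44.4%, 24.6 to 66.3; Fisher's exact test, adjusted p = 0.102, 0.0231 to 1 over its alternatives), with Elavl4 (11.6), Rbfox3 (6.33), Nefm (6.25) and Nefl (5.94) highest, below CpG-matched lists at 75.1% (permutation adjusted p = 0.0080). In the replicates' own lists, which were not tested against matched lists, 12 of 18 and 11 of 18 neuronal genes had a peak. Cardiomyocyte genes had a peak in 6 of 14 (42.9%, 21.4 to 67.4; Fisher's exact test, adjusted p = 0.108; CpG-matched permutation adjusted p = 1), led by Hcn4 (10.9), Ryr2 (8.91), Tnni3 (5.82) and Gata4 (4.06), and in 9 of 14 and 8 of 14 in the lists of replicates 1 and 2.

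All listed housekeeping and cell cycle genes were marked. The 16 housekeeping genes (Fisher's exact test, adjusted p = 0.00759) included Actb (42.5), Eef2 (41.7), Ywhaz (38.4) and Rpl13a (36.2). Their median fold of 28.5 exceeded that of every CpG-matched random list (median of the matched medians 15.9). The 18 cell cycle genes (Fisher's exact test, adjusted p = 0.00313) had a median fold of 17.1, near the median of the matched medians of 17.3. Aurka (26.7, a peak shared with Cstf1), Mki67 (20.3), Mcm6 (19.2) and Mcm4 (18.6) were highest. The shares of 100% in both lists were not separated by the test from the 88.2% and 96.3% of CpG-matched lists (permutation adjusted p = 0.140 and 1). No share can exceed 100%, so that test could not have called an excess here. Over the alternatives of Fisher's exact test the adjusted p ranged from 0.0065 to 0.0186 for housekeeping and from 0.00121 to 0.00764 for cell cycle genes.

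**Figure D3:**
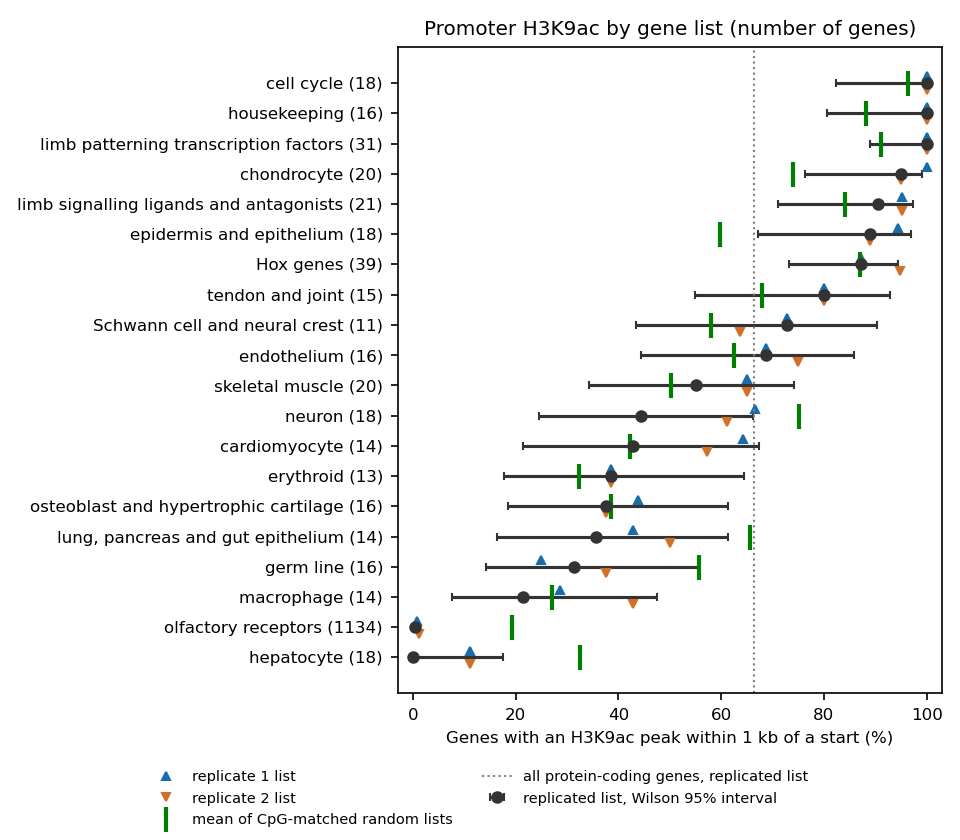
Share of genes with an H3K9ac peak within 1 kb of a start (percent, x axis) for the 20 gene lists (y axis, number of genes in brackets), in the replicated list with Wilson 95% intervals and in each replicate's own list; green ticks are means of CpG-matched random lists and the dotted line is all coding genes (66.4%). Limb patterning, cell cycle and housekeeping genes stand at 100%, hepatocyte genes at 0%.

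Peaks away from promoters were examined in 12 intervals around limb genes. The gene desert centromeric of HoxD, which holds digit enhancers, contained 14 replicated peaks more than 1 kb from any start (18.9 per Mb, percentile 86.7 of random intervals of its length), and the telomeric desert contained 11 (14.1 per Mb, percentile 81.5). The HoxC cluster had 10 (86.4 per Mb, percentile 98.7; permutation p = 0.0292, adjusted p = 0.350 over 12 intervals) and the interval between Tbx5 and Tbx3 had 8 (54.1 per Mb, percentile 96.8; permutation adjusted p = 0.432). The HoxA, HoxD and HoxB clusters stood at percentiles 93.8, 92.2 and 89.5. The interval from Shh to Lmbr1, which contains the limb enhancer of Shh, held 1 such peak, and the Gli3 and Grem1 intervals held 1 each, the Dlx5 interval 2 and the Sox9 desert 4 (percentiles 36.8, 60.5, 52.5, 54.7 and 42.1). The Shh peak lies within the Shh gene (chromosome 5, 28464399 to 28465111), and the rest of that interval held no such peak. The Grem1 peak (chromosome 2, 113756804 to 113757054) lies close to the Grem1 start at 113758646. None of the 12 passed the adjusted threshold. In single replicates' own lists the Dlx5 interval stood at percentiles 31.9 and 33.0 and the Shh interval at 56.2 and 30.5 (replicates 1 and 2). Including promoters, replicated peaks covered 58.8% of the HoxA cluster, 40.7% of HoxD, 24.9% of HoxC and 4.35% of HoxB.

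The 5 strongest replicated peaks farther than 5 kb from any start were in an intron of the noncoding gene Lncppara (fold 37.2; chromosome 15, 85669380 to 85673365), in an intron of Tns3 (27.3; chromosome 11, 8621137 to 8625770), and in intergenic sequence with Ptma (25.6; chromosome 1, 86487704 to 86488818), Chd2 (25.2; chromosome 7, 73616824 to 73618408) and Spag6 (24.7; chromosome 2, 18766322 to 18767745) as the nearest coding gene. Ppara was the nearest coding gene to the first, 61618 bp away. In total 11623 replicated peaks (27.0%) lay farther than 5 kb from a start, with a median fold of 3.28.

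CpG-rich promoters were nearly all marked. Of genes with a promoter observed/expected CpG of at least 0.6, 9791 of 10060 (97.3%) had a peak, against 4753 of 11851 (40.1%) below it, a difference of 57.2 percentage points. CpG was measured at the outermost start, which for some genes is not the marked one. Prrx1 and Tbx4 were in the CpG-poor class and their peaks covered that start.

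Genes on the X chromosome were marked less often than autosomal genes. On the X 451 of 948 coding genes (47.6%) had a promoter peak, against 14089 of 20780 (67.8%) on the autosomes (Fisher's exact test, two-sided, p = 5.10e-36). The housekeeping genes Hprt (12.7) and Pgk1 (10.3), both X-linked, were among the 4 housekeeping genes with the lowest promoter folds, with Polr2a (13.3) and B2m (11.5). Within CpG-rich promoters the shares were 90.9% and 97.5% (Fisher's exact test, p = 2.61e-07), and within CpG-poor ones 31.7% and 41.3% (Fisher's exact test, p = 4.88e-07). Replicated peaks numbered 4.64 per Mb on the X and 17.6 on the autosomes (ratio 0.263), where single autosomes ranged from 10.8 to 34.3. The ratio was 0.197 in replicate 1, 0.176 in replicate 2 and 0.134 in the pooled list. The Y chromosome had 4 replicated peaks, at Kdm5d (5.62), Eif2s3y (4.06), Uty (6.56) and Ddx3y (5.62).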

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

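Outside the chromosomes analysed, 7 replicated peaks lay on 3 scaffolds. They are listed because they were not used above and exceed the 3 that a count of 0 allows, which says only that peaks are present there, since some of these scaffolds carry annotated genes. They had folds of 1.60 to 12.2, and those overlapping an annotated coding gene were at CAAA01118383.1 (12.2), Tmlhe (9.84) and Vamp7 (5.47).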

How the results depend on the processing

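Over 46 results and 309 alternatives, 253 kept their side of the threshold or their value, 26 values moved, 20 calls were lost, 10 were gained and no call changed sign. The causes were not tested. Of the 20 gene lists, 7 kept their side of the threshold in every alternative and 13 did not. Peaks found in both replicates and genes without a neighbouring start were alternatives chosen after seeing the data.

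Replicate 1 peaks found in replicate 2 were 53.2% with 1 bp of overlap, 35.9% with 50% of both peaks, 55.0% at a −log10 q of at least 2 and 44.7% with lists of equal length, and replicate 2 peaks found in replicate 1 were 41.4%, 27.5%, 51.1% and 44.8%. Replicated peaks found in both were 79.5%, 54.1% and 61.2% under the first 3 of these (the q limit on all lists), those found in replicate 1 were 72.8% and 77.0% under the latter 2, and those found in replicate 2 were 89.4%, 70.7% and 74.8% under all 3. The promoter share was 47.9% with a window of 500 bp, 63.4% with 2.5 kb, 29.6% in the pooled list, 60.7% for peaks found in both replicates, and 34.5% to 40.4% leaving out a replicate. Ranked on −log10 p, decile 10 of replicate 1 was recovered in 18.4%. The X to autosome density ratio was 0.134 in the pooled list and 0.176 to 0.197 leaving out a replicate.

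Differences of gene lists from other genes are in percentage points. Against CpG-matched lists, calls were lost for limb patterning factors (8.95), signalling (6.43), Hox (0.242), osteoblast (-0.969), macrophage (-5.70), germ line (-24.5), housekeeping (11.8) and cell cycle genes (3.69), and gained for epidermis (29.2) and neuron (-30.7). Limb patterning, housekeeping and cell cycle genes were all marked, so against matched lists no excess could have been called for them. With the pooled list they were lost for macrophage (-27.7), lung, pancreas and gut (-6.23) and germ line (-20.5), and gained for epidermis (29.5) and erythroid (-32.1). With outermost starts, signalling was lost (23.2) and neuron (-29.2) and cardiomyocyte (-34.0) were gained. Osteoblast was lost with a 2.5 kb window (-23.8), at a −log10 q of at least 2 (-28.8) and among genes without a neighbouring start (-24.2), where lung, pancreas and gut was lost too (-30.9) and epidermis gained (26.6). Cardiomyocyte was gained with a 500 bp window (-30.0) and for peaks found in both replicates (-29.6). Leaving out each replicate gave -31.4 to -23.8 for osteoblast, 20.0 to 26.9 for epidermis, -39.0 to -26.1 for macrophage and -24.7 to -18.9 for lung, pancreas and gut, with a call changed in at least 1 of the pair. Among lists not past the threshold the sign of the difference from other genes varied between alternatives for 5. These were neuron (-29.2 to 1.71), cardiomyocyte (-34.0 to 0.917), endothelium (-12.6 to 23.3), skeletal muscle (-15.7 to 4.49) and Schwann cell genes (-5.29 to 14.3). Erythroid was below other genes in every alternative, and 6.06 above CpG-matched lists. No interval passed the threshold in any alternative. The HoxA, HoxD and HoxC clusters and the Tbx5 to Tbx3 interval came closest, by share of bases covered (percentiles 99.1, 98.8, 98.7 and 98.8, permutation adjusted p = 0.0768 each). By that measure the next lowest was the HoxB cluster (permutation adjusted p = 0.559). Leaving out each replicate, the Dlx5 interval stood at percentiles 31.9 to 33.0 and the Shh interval at 30.5 to 56.2. Read totals are unknown, and the part that depth plays in the weak peaks was not tested.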

Other observations

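Gene families outside the fixed lists, chosen after the data were seen, ranged from 0% to 97.5% of genes with a promoter peak, with no test between them. Ribosomal protein genes had a promoter peak in 78 of 80 cases (97.5%, 91.3 to 99.3) with a median fold of 27.1 among those marked, clustered histone genes in 59 of 67 (88.1%, 78.2 to 93.8) with 11.04, and zinc finger genes named Zfp in 315 of 365 (86.3%, 82.4 to 89.5) with 16.2. Clustered protocadherins, cell adhesion genes of neurons, had a peak in 10 of 56 cases (17.9%, 10 to 29.8) with a median fold of 3.52. Keratin-associated proteins had 2 of 57 (3.51%, 0.968 to 11.9), vomeronasal receptors 1 of 326 (0.307%, 0.0542 to 1.72) and defensins 0 of 64 (upper bound 5.66%, with 1 and 2 in the lists of replicates 1 and 2). The strongest replicated peak of all (fold 63.9; chromosome 7, 73555967 to 73558588) is a promoter peak that covers annotated starts of the noncoding gene 1810026B05Rik, and the nearest start of a coding gene, Chd2, is 14137 bp away.

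Widths of runs of H3K9ac were compared between lists after the widest runs had been seen, several of them over patterning genes. Counting each run once, the 24 runs at limb patterning factors had a median width of 10696 bp, against 3895 bp for 16 housekeeping, 3048 bp for 18 cell cycle and 4101 bp for 19 chondrocyte runs. Without the 3 patterning runs that were among the 10 widest of all (HoxA, HoxD and Lmx1b), the median of the other 21 was 8735 bp (permutation p = 0.00294 against housekeeping, 0.000100 against cell cycle and 0.00126 against chondrocyte runs; adjusted over the 3 comparisons at most 0.00294). These p-values describe runs picked up on the same data and are not independent evidence. Median promoter fold was 20.8 for all 24 patterning runs, against 28.5 for housekeeping (permutation p = 0.171), 17.1 for cell cycle (permutation p = 0.00678) and 11.6 for chondrocyte runs (permutation p = 0.00488).

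The tests on peak counts and on CpG classes of X-linked genes below were chosen after the results were seen, and the tests on X dose and on other tissues' genes before. Replicate 2 had 95631 peaks against 73200 in replicate 1, a ratio of 1.31, although its background pileup was lower. The ratio was 0.946 (0.925 to 0.967, exact interval) at a −log10 q of at least 10 and 1.09 at a −log10 q of at least 2. At that last limit replicate 1 had 50144 peaks and replicate 2 had 54537, so most of replicate 2's excess lay among weaker calls below it. Whether weak calls near the authors' limit account for all of it stays open. Lower depth (1.36 times per bp) also lowers the count of peaks at a given q. Sites marked in replicate 2 alone stay open too: 40.4% of its 60493 peaks without a partner had a −log10 q of at least 2, against 85.6% of those with a partner and 50.9% of replicate 1's peaks without one. No biological explanation was tested, since both replicates belong to one group.

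The lower share of marked promoters on the X chromosome was set against promoter type and gene dose. The X has fewer CpG-rich promoters (26.8% of coding genes against 47.2%), but within that class its share was still lower (a difference of -6.57 percentage points), which argues against promoter type as the whole cause. Among marked CpG-rich promoters the median fold was 9.53 on the X (231 genes) and 17.5 on the autosomes (9556 genes), a ratio of 0.543 (0.504 to 0.584, bootstrap over genes), while the medians of the 19 autosomes ranged from 16.7 to 18.7. The ratio was 0.571 in replicate 1 and 0.569 in replicate 2, but over all peaks, promoter or not, the median fold was higher on the X than on the autosomes in every list (6.25 against 4.06 in the replicated list). Those medians are over unlike sets of peaks, with fewer weak ones on the X. In the pooled list 87.6% of X peaks had a −log10 q of at least 2, against 69.4% of autosomal peaks. A lower dose of active X copies is a candidate explanation; fewer X copies in male embryos and inactivation in female embryos were not separated, and no biological explanation was tested against a group of the design.

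Of 107 genes in the 7 lists of blood cells and tissues outside the limb other than olfactory receptors, 32 had a promoter peak, with a median fold of 5.43. Those with a peak were CpG-rich in 12 of 32 cases (37.5%) and those without in 11 of 75 (14.7%). The difference was 22.8 percentage points (5.32 to 41.2, Fisher's exact test, p = 0.0188). Over all coding genes CpG-rich promoters were also marked more often (97.3% against 40.1%). A difference in this direction is therefore not particular to these genes, and the test cannot decide whether promoter class accounts for part of their peaks. Among the 5 with a fold of at least 10, 40% (5.27 to 85.3, exact interval) shared the peak with another coding gene's start, against 24.8% of all 10298 genes that strong. They were Sftpc with Bmp1 and Gdf9 with Uqcrq, and 5 genes are too few to decide. In replicate 2's own list no peak reached the Sftpc window. Klf1, Elavl4 and Hcn4 had no other coding start at the peak. No biological explanation was tested.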
